A study of Mus musculus with 5 samples.

How the data were processed

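RNA from the forelimb buds of mouse embryos at E11.5 was measured on 5 single-channel Affymetrix arrays, 2 from double mutant embryos and 3 from wild type embryos. Per the labels, the embryos were of the C57Bl/6 strain and each sample came from unpooled embryos, so the replicates were taken as separate animals. The sex-linked transcripts described below leave it uncertain whether each of the 2 double mutant arrays held RNA of a single embryo. Limbs went from cold buffer straight into Qiazol, per the labels' protocols, and RNA was purified on columns after proteinase K and DNase steps. Biotin labelling used a kit with 2 rounds of amplification, per the labels' protocols. Such labelling starts from the poly-A tail and favours the 3' end of each transcript, so that probe sets lying at different distances from the tail can respond differently to RNA quality and to the labelling reaction.

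The deposited values were linear intensities, 1 value per probe set and array. The submitters' processing notes name RMA and limma, with no version, role or order. RMA itself returns log2 values, so the deposited intensities had been put on a linear scale at a step not given in the sources used here. Background correction, normalization and summarization settings were not given in the sources used here either. The deposited intensities were already comparable between arrays, with medians from 39.4 to 44.4, lowest values from 4.82 to 5.53 and highest values from 22487.9 to 22950.5. They were not normalized again, and log2 was taken before every test. The tests had been written for log2 values with this step foreseen.

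Of 45101 probe sets, 64 manufacturer controls were left out and 45037 were tested, with no filter on level. Of the tested probe sets, 34945 carried 1 gene symbol in the platform annotation used here, 932 carried several and 9160 carried none, and only those with 1 symbol were named. The gene identifiers of 34741 of them matched the reference gene table, which changed 0 symbols. The probe sets with 1 symbol stood for 18193 genes. Where 1 value per gene was needed, the probe set with the highest mean over the 5 arrays was taken. Equal values in all 5 arrays occurred in 472 probe sets, and 21842 had a value repeated in at least 2 arrays. No genomic positions of the probes were used.

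Groups were compared with limma 3.58.1 in R 4.3.3, with a linear model of 1 mean per genotype, no covariate, and empirical Bayes moderation without trend. The fit had 3 residual and 1.29 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 45037 probe sets, and a probe set was called at an adjusted p under 0.05. A second count took probe sets at an unadjusted p under 0.01 and a change of at least 1.5-fold. Differences are given as double mutant minus wild type on the log2 scale with limma's standard error, and levels as mean log2 intensity ± SD over 2 double mutant and 3 wild type arrays. With 5 arrays, their number limits the precision.

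Lists of genes for the limb territories, signalling pathways, cell types and general processes were tested with limma's camera at a preset correlation of 0.01, on 1 probe set per gene, with Benjamini-Hochberg adjustment over 33 lists. Camera asks whether a list is shifted relative to all other genes. Camera with an estimated correlation and fry were the alternatives. The lists, the tests, the thresholds, most of the other settings tried and the rule for naming genes were chosen before the data were examined. The ribosomal list was built from the symbol prefixes Rpl and Rps and so also holds ribosomal S6 kinases such as Rps6kb2.

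The rule named every probe set of Sost and Sostdc1. It also named the 12 genes with the largest rise and the 12 with the largest fall at an adjusted p under 0.05 whose arrays did not overlap between the groups, leaving out provisional symbols. From each list it named up to 3 members with the smallest p, plus 16 limb patterning genes in any case. Genes named outside this rule complete a count of called list members or were chosen after their values were seen.

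The difference between the 3' and the 5' control probe sets of Gapdh and Actb was compared by an exact permutation test over the 10 splits of 5 arrays into 2 and 3, whose smallest possible p is 0.1. Non-mouse control transcripts were averaged over their probe sets in each array. For the neighbours of the targeted genes, gene order came from the GRCm38.p6 annotation, used for order alone.

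The fit and the set test were tested on simulated data of 45037 probe sets in the same 2 against 3 design, with 200 probe sets changed, 50 per size. The share recovered was 14% at a 1.5-fold change, 46% at 2-fold, 82% at 4-fold and 88% at 8-fold, with 2 false calls. Camera called the 5 shifted sets and none of the unshifted ones. The simulated probe sets varied independently, so false calls from correlated genes were not tested. In the arrays the estimated correlation reached 0.748, in the fibrillar matrix list. Small changes were therefore often missed in the simulation. The real fit called 8206 probe sets, which makes the adjusted threshold less strict, so these shares do not give its power.

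The other settings fixed in advance were a second quantile normalization, equal array medians, a filter on dim probe sets, a trended robust variance model, array weights, the brightest or the mean probe set per gene before the fit, each array left out in turn, a block for the number in the sample names, and covariates for the Y-linked level and the 3' to 5' difference. Other thresholds and set tests were also fixed in advance. After the data were seen, the second brightest probe set per gene, a fit on probe sets with 1 symbol, and list tests without genes called in both directions were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.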

Results

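Gene expression was measured in forelimb buds of mouse embryos at E11.5, when the hand plate forms and the digit territory is patterned. The arrays fell into 2 groups, 2 from embryos lacking both Sost and Sostdc1 and 3 from wild type embryos. Sost encodes sclerostin, a secreted protein that binds Wnt co-receptors of the LRP family and blocks canonical Wnt signalling, and Sostdc1 encodes a related secreted antagonist of Wnt and BMP signals. The study's title ties both genes to the number of digits and to Gli3, the main transcriptional repressor of the Hedgehog pathway in the limb. The single comparison of the design therefore asked how the forelimb transcriptome differed when both antagonists were missing. Median array intensities lay between 39.4 and 44.4 on the linear scale.

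Signal for each targeted gene fell in the double mutants on 1 of its 2 probe sets. Sost on 1450179_at had a mean log2 intensity of 4.29 ± 0.19 (SD, n = 2) in double mutants and 6.47 ± 0.28 (SD, n = 3) in wild type, a difference of −2.17 ± 0.20 (SE, adjusted p = 0.0091). Sostdc1 on 1460250_at had 6.82 ± 0.76 in double mutants and 9.17 ± 0.24 in wild type, a difference of −2.35 ± 0.37 (SE, adjusted p = 0.0233). The other Sost probe set, 1421245_at, was dim in both groups, at 3.83 ± 0.27 and 4.55 ± 0.50 (adjusted p = 0.237). The other Sostdc1 probe set, 1449340_at, stood at 8.93 ± 0.04 in double mutants and 8.89 ± 0.13 in wild type (adjusted p = 0.775). The deleted part of each gene and the place of each probe set were not known here, and a probe set outside the deleted part checks nothing. With 1 array left out at a time, the Sost difference lay between −2.03 and −2.32 and the Sostdc1 difference between −1.82 and −2.89, and both calls were lost without double mutant replicate 1 (adjusted p = 0.0675 and 0.0645) or wild type replicate 2 (adjusted p = 0.0595 and 0.103). The Sost call was also lost without double mutant replicate 2 (adjusted p = 0.0529), the Sostdc1 call without wild type replicate 1 or 3 (adjusted p = 0.0897 and 0.0810) or with a covariate for the Y-linked level (adjusted p = 0.0793), and both with a replicate block (adjusted p = 0.0822 and 0.144) or a covariate for the 3' minus 5' difference (adjusted p = 0.110 and 0.224).

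**Figure D1:**
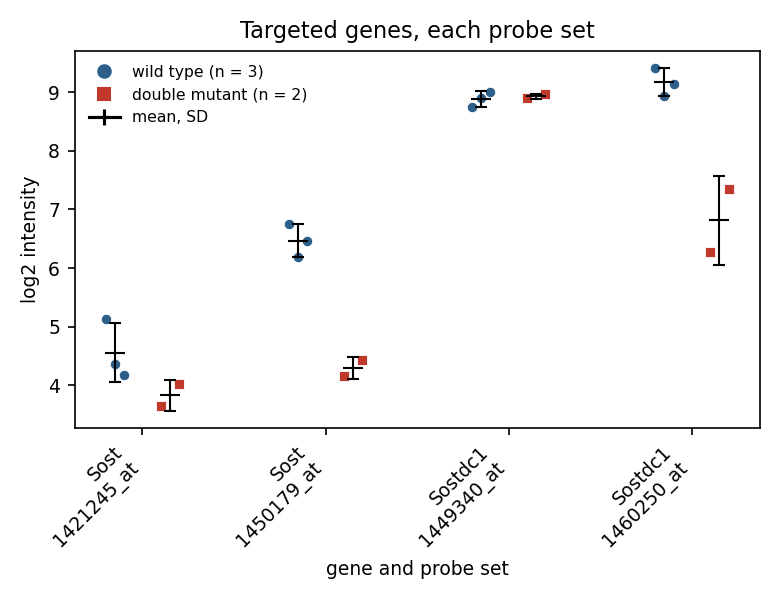
Log2 intensity of the 4 Sost and Sostdc1 probe sets in each array, with circles for the 3 wild type arrays, squares for the 2 double mutant arrays, and bars for mean and SD. Sost 1450179_at (mean 4.29 against 6.47) and Sostdc1 1460250_at (6.82 against 9.17) were called lower in double mutants, and the other probe set of each gene was not called.

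By the brightest probe set of each gene, the largest rise was that of Pik3cd, which encodes a catalytic subunit of phosphoinositide 3-kinase, from 7.51 ± 0.21 (SD, n = 3) in wild type to 12.78 ± 0.11 (SD, n = 2) in double mutants, a log2 difference of 5.27 ± 0.15 (SE, adjusted p = 0.0048). The rise was on 1443798_at alone, and the 5 other Pik3cd probe sets differed by −0.11 to 0.07. Of those 5, 0 lay above the median level of all probe sets, so a change could be missed on them. Whether 1443798_at reports the Pik3cd transcript was not tested. Next came Taf15, an RNA-binding protein linked to transcription (3.61 ± 0.61), the channel gene Trpc2 (3.37 ± 0.38), the zinc finger gene Zfp945 (3.28 ± 0.26), the histone gene H3f3a (2.95 ± 0.54) and the axon guidance receptor Robo2 (2.86 ± 0.33). Zfp874a, Vps52, the heat shock factor Hsf2, the antisense transcripts Hoxd3os1 and Rab26os, and Cox7c of the respiratory chain rose by 2.46 to 2.83. In wild type Robo2, Zfp874a and Hsf2 were dim (3.54, 3.64 and 4.16, against 3.07 for Trpn, a control for an absent transcript), which leaves the size and rank of their rises uncertain. Taf15, Trpc2, Zfp945, H3f3a, Vps52 and Rab26os stood at 5.04 to 5.40 in wild type, also below the median level of all probe sets (5.41). H3f3a had 0 other probe sets above that level. Whether such probe sets report the main transcript of their gene was not tested. Adjusted p over these 12 genes ran from 0.0048 to 0.0325. Trpc2 also rose on its second probe set (2.08 ± 0.25, adjusted p = 0.0137). Zfp945 and Vps52 each had another probe set called lower (−2.35 and −1.16), and the second Taf15 probe set stood at −1.46 (adjusted p = 0.0657).

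On the same basis the largest falls were those of Gdpd3, a phosphodiesterase gene (−2.87 ± 0.20, SE), Nog, which encodes the secreted BMP antagonist noggin (−2.48 ± 0.14), the protease gene Ctse (−2.47 ± 0.25), the transcription factor gene Tox (−2.45 ± 0.17) and Scpep1 (−2.45 ± 0.14). Mlf2, Ncstn, Gpatch11, Smn1, Hoxa13, Anxa6 and Sdr39u1 differed by −2.34 to −2.25, and Hoxa13 is the homeobox gene of the distal limb. Adjusted p over these 12 genes ran from 0.0053 to 0.0167. Nog stood at 3.98 ± 0.15 in double mutants and 6.46 ± 0.18 in wild type, and Gpatch11 at 3.97 and 6.30, and their dim levels in double mutants leave the size and rank of these falls uncertain. Tox and Anxa6 each fell on a second probe set (−0.81 and −3.12), while 2 dimmer Anxa6 probe sets (2.47 and 1.70) and a dimmer Ncstn probe set (1.23) were called higher. Ctse and Scpep1 each had 1 other probe set above the median level of all probe sets, and it was not called. Smn1 encodes the survival motor neuron protein, and Ncstn a subunit of gamma-secretase, the protease that cleaves Notch.

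Beyond these genes, limma called 8206 of 45037 probe sets (18.2%), 3919 higher and 4287 lower in double mutants, with 1852 at least 2-fold higher and 1831 at least 2-fold lower. At an unadjusted p under 0.01 and at least 1.5-fold, 5971 probe sets passed, 2875 higher and 3096 lower. At that p and any fold there were 8493, against 450 expected by chance. The 2 groups did not overlap in 45.2% of all probe sets, where chance gives 20%. By the brightest probe set of each gene, 1194 genes rose and 1481 fell. Arrays correlated at 0.991 to 0.995 within a group and at 0.954 to 0.969 between groups (Pearson r across probe sets, which are not independent replicates), and the first principal component took 81.0% of the variance and separated the genotypes. The count fell to 0 with limma when double mutant replicate 1 or wild type replicate 2 was left out, with 14059 and 11115 probe sets at an unadjusted p under 0.05.

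Transcripts that come from no mouse gene also differed between the groups. The poly-A spike-in Dap, added to RNA before labelling, had a mean log2 intensity of 7.09 ± 0.27 (SD, n = 2) in double mutants and 3.30 ± 0.06 (SD, n = 3) in wild type. The spike-ins Thr, Phe and Lys stood at 5.23, 5.35 and 4.86 in double mutants and at 3.50, 3.54 and 3.31 in wild type. Wild type levels lay near that of Trpn, the control for an absent transcript (3.07 ± 0.02), so the spike-in differences are lower bounds. The hybridization controls BioB, BioC, BioD and Cre, added after labelling, differed by −0.41 to −0.27. The 3' minus 5' difference of Gapdh was 0.21 ± 0.08 in double mutants and −0.10 ± 0.04 in wild type (exact permutation p = 0.1, the smallest possible), and that of Actb was 0.60 ± 0.07 and 0.37 ± 0.27 (exact permutation p = 0.4). Each group therefore had its own spike-in level, and preparation and genotype cannot be told apart in any of the differences given here.

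Xist, the RNA that coats the inactive X chromosome, and transcripts of the Y chromosome were both high in the double mutant arrays. On 1436936_s_at, Xist stood at 12.37 and 11.75 in double mutant replicates 1 and 2, at 12.28 in wild type replicate 1, and at 5.73 and 5.70 in wild type replicates 2 and 3. The Y-linked gene Eif2s3y stood at 8.36 in both double mutant arrays, at 3.20 in wild type replicate 1, and at 8.49 and 8.42 in wild type replicates 2 and 3. Kdm5d and Uty, also Y-linked, were likewise low in wild type replicate 1 and high in the other 4 arrays. In the sex-linked list limma called 0 of 4 measured members between the genotypes, 0 reached an unadjusted p under 0.05, and camera gave an adjusted p of 0.460.

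**Figure D2:**
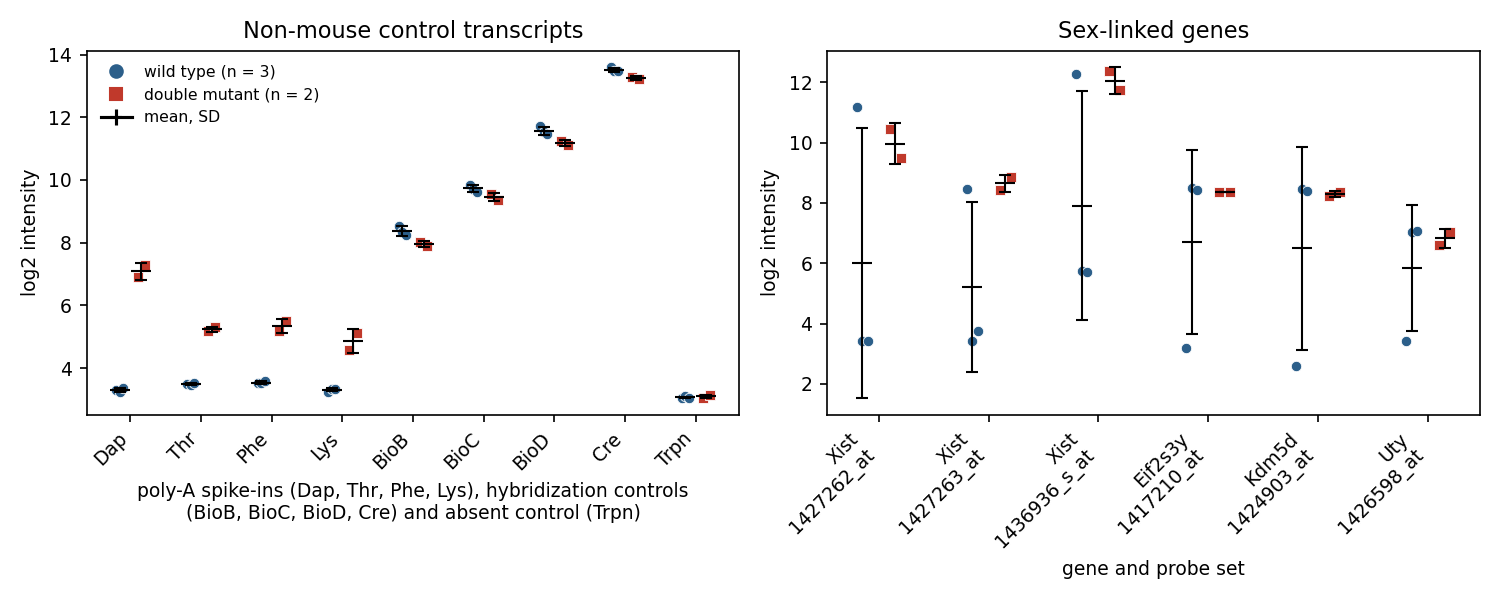
Log2 intensity in each array of non-mouse control transcripts (left, mean of their probe sets) and of sex-linked genes by probe set (right), with circles for wild type (n = 3), squares for double mutant (n = 2), and bars for mean and SD. The spike-in Dap stands at 7.09 in double mutants and 3.30 in wild type, and both double mutant arrays are high for Xist and for Eif2s3y, at 8.36.

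Among canonical Wnt feedback and target genes, 3 of 18 measured members rose, 1 fell and 14 were not called. Dkk1, a secreted Wnt inhibitor induced by the pathway, rose by 0.81 ± 0.14 (SE, adjusted p = 0.0283), from 7.59 ± 0.12 to 8.40 ± 0.25 (SD). Notum, which inactivates Wnt proteins, rose by 0.72 ± 0.15 (adjusted p = 0.0417), and Dkk4 by 0.98 ± 0.20 (adjusted p = 0.0423). Ccn4, earlier known as Wisp1, fell by 0.61 ± 0.11 (SE, adjusted p = 0.0295). Axin2, a common readout of the pathway, stood at 9.07 ± 0.06 in double mutants and 9.12 ± 0.19 in wild type (adjusted p = 0.831), while its second probe set was called lower (−1.66 ± 0.25). Lef1 stood at 10.05 ± 0.27 and 9.54 ± 0.18 (adjusted p = 0.118), and its second probe set at −0.94 (adjusted p = 0.0938). The counts were the same adjusted over the list alone, and the list as a whole gave an adjusted p of 0.323 with camera.

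Among Wnt ligands, receptors and secreted modulators, 3 of 42 members rose and 5 fell, with 4 and 5 adjusted over the list alone. Lrp4, a receptor that binds sclerostin and the Sostdc1 protein, rose by 0.70 ± 0.08 (SE, adjusted p = 0.0123), and the ligand genes Wnt6 and Wnt5a rose by 0.88 ± 0.16 and 0.63 ± 0.14. The second Wnt5a probe set stood at −0.07 (adjusted p = 0.677). The receptor genes Fzd8 (−0.77 ± 0.11) and Fzd6 (−0.45 ± 0.06), the ligand gene Wnt2 (−0.84 ± 0.16), the antagonist gene Sfrp1 (−0.64 ± 0.11) and the R-spondin gene Rspo3 (−0.46 ± 0.08) were lower. Calls on other probe sets of this list were 3 higher and 12 lower. The list was not called (adjusted p = 0.961 with camera).

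In the Hedgehog list 3 of 15 members rose and 0 fell, with the same counts adjusted over the list alone. Gli1, a direct transcriptional target of the pathway, rose by 1.20 ± 0.12 (SE, adjusted p = 0.0098), from 6.64 ± 0.11 (SD, n = 3) to 7.85 ± 0.19 (SD, n = 2). The receptor gene Ptch1 rose by 0.38 ± 0.07 (adjusted p = 0.0296), and the transducer gene Smo by 0.46 ± 0.09 (adjusted p = 0.0348). Both had another probe set called lower, at −1.36 ± 0.17 for Ptch1 and −0.62 ± 0.11 for Smo, and a dimmer Ptch1 probe set was called higher (1.78 ± 0.37). With equal array medians neither gene was called on its brightest probe set. Shh itself stood at 8.22 ± 1.19 in double mutants and 6.39 ± 0.60 in wild type (adjusted p = 0.141), a spread too wide for a call. Gli3 stood at 10.15 ± 0.70 and 10.40 ± 0.10 (adjusted p = 0.625), with a dimmer probe set called lower (−1.88 ± 0.34), and Hhip at 5.36 ± 0.09 and 5.41 ± 0.42 (adjusted p = 0.921). The Hedgehog list gave an adjusted p of 0.460 with camera, with direction up, mean 0.17 and median −0.05. Calls on other probe sets of its members were 1 higher and 5 lower.

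In the posterior limb list, which shares Shh, Ptch1 and Gli1 with the Hedgehog list, 3 of 14 members rose and 2 fell, with 4 and 2 adjusted over the list alone. Hoxd12 fell by 2.12 ± 0.21 (SE, adjusted p = 0.0098) and Hoxd11 by 1.36 ± 0.15 (adjusted p = 0.0126), both homeobox genes of the distal and posterior limb, while Tbx2 rose by 0.35 ± 0.04 (adjusted p = 0.0145). Hand2, which promotes Shh expression, stood at 11.67 ± 0.01 and 11.71 ± 0.06 (adjusted p = 0.678) on its brightest probe set, and at −1.83 and −1.75 on 2 dimmer ones, both called. Grem1, the BMP antagonist that relays Shh signal to the apical ridge, stood at 8.06 ± 0.75 and 7.25 ± 1.19 (adjusted p = 0.537). In the anterior list 1 of 11 members, Alx4, was lower (−0.45 ± 0.10, adjusted p = 0.0467), at dim levels of 3.63 ± 0.05 and 4.08 ± 0.14, and 0 of 11 passed adjusted over the list alone. The camera test gave adjusted p of 0.238 for the posterior and 0.804 for the anterior list. Calls on other probe sets were 2 higher and 6 lower for the posterior list and 0 higher and 2 lower for the anterior list.

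**Figure D3:**
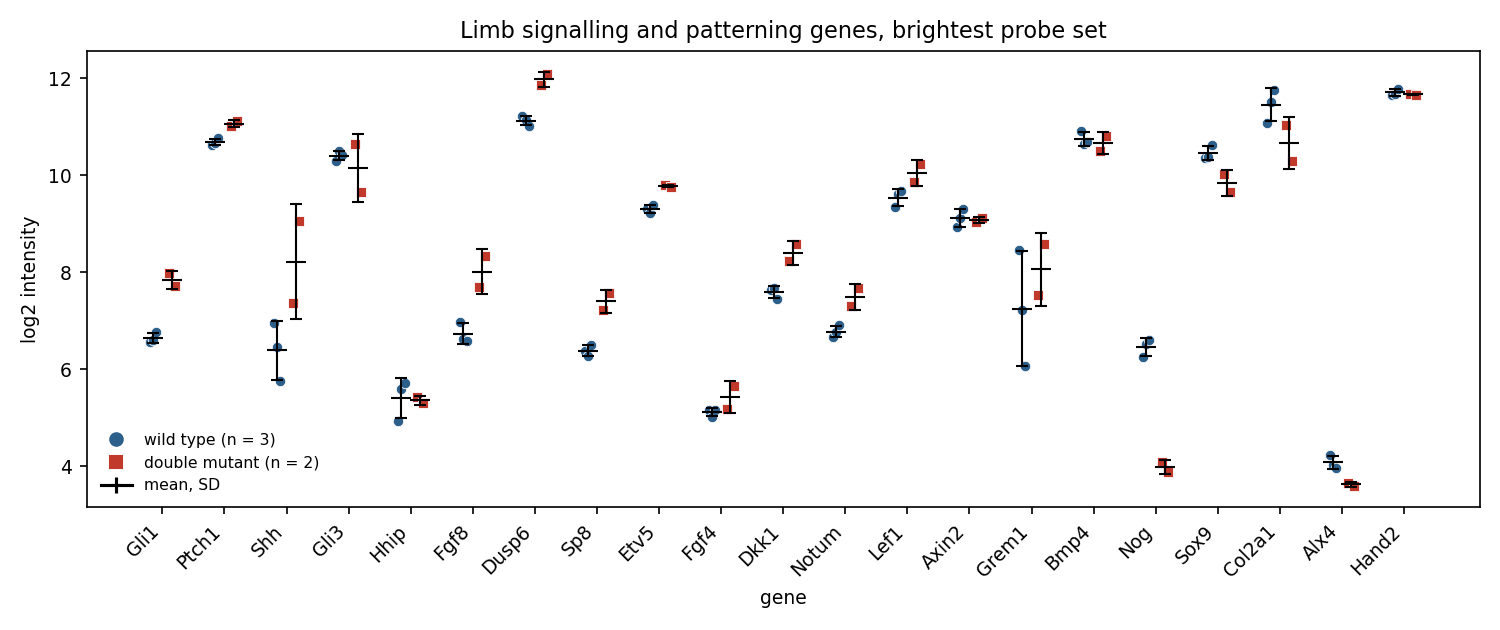
Log2 intensity in each array of limb signalling and patterning genes on the brightest probe set of each, with circles for wild type (n = 3), squares for double mutant (n = 2), and bars for mean and SD. Gli1, Fgf8, Dusp6 and Sp8 are higher and Nog is lower in both double mutant arrays, while Axin2, Hand2 and Bmp4 overlap between the groups.

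Distal and proximal genes were called in both directions. In the distal list Hoxa13 (−2.29 ± 0.30, SE) and Hoxd12 were lower and Wnt5a was higher among 14 members (2 higher and 2 lower adjusted over the list alone), and in the proximal list Osr2 fell by 2.12 ± 0.20, Scube2 by 0.61 ± 0.11, while Hoxa9 rose by 0.49 ± 0.06 and Pbx3 by 0.88 ± 0.14 among 10. The camera test gave adjusted p of 0.883 for the distal and 0.804 for the proximal list. Hoxc5, in the forelimb list, fell on all 3 of its probe sets (−2.39 to −0.51) and was the 1 called of 3 members (adjusted p = 0.883 for the list). Tbx5, the forelimb identity gene, stood at 10.77 ± 0.18 and 10.20 ± 0.54 (adjusted p = 0.335), with another probe set at −1.89 (adjusted p = 0.064). In the hindlimb list, which includes Pitx1 (5.08 and 5.01), limma called 0 of 4, and 0 reached an unadjusted p under 0.05 (list adjusted p = 0.551). The proximal list (mean −0.11, median 0.016) and the forelimb list (mean −0.05, median 0.13) had means and medians of opposite sign, and camera pointed up for the first and down for the second. Counts for the proximal, forelimb and hindlimb lists were the same adjusted over the list alone.

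The list for the apical ridge, the ectodermal rim that drives limb outgrowth, and for the FGF signalling it sends was shifted up with camera at the preset correlation. Of 23 members 6 rose and 0 fell, with 9 and 0 adjusted over the list alone, and the median difference was 0.23 (camera adjusted p = 0.0064, and adjusted p = 0.909 with an estimated correlation). Fgf8, the main ridge FGF, rose from 6.73 ± 0.21 (SD, n = 3) to 8.02 ± 0.46 (SD, n = 2), by 1.29 ± 0.25 (SE, adjusted p = 0.0364). Sp8, a transcription factor needed for the ridge, rose by 1.02 ± 0.14 (adjusted p = 0.0167). Dusp6, a feedback inhibitor induced by FGF signalling, rose by 0.86 ± 0.10 (adjusted p = 0.0137), with smaller rises of Dlx2 (0.75 ± 0.16), Etv4 (0.56 ± 0.08) and Etv5 (0.48 ± 0.07). For Etv5, 2 other probe sets were called lower (−1.49 and −3.56). Fgf4 stood at 5.43 ± 0.34 and 5.11 ± 0.08 (adjusted p = 0.28). Other probe sets of ridge members were called higher in 3 cases and lower in 7. The ridge list was not called without double mutant replicate 2 (median 0.12, adjusted p = 0.0556), by the mean probe set per gene (0.0075, adjusted p = 0.668) or by the second brightest probe set of the 12 members that had one (−0.46, adjusted p = 0.656).

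The ectoderm list was shifted up at the same setting. Of 17 members 5 rose and 1 fell, with 7 and 1 adjusted over the list alone, and the median was 0.40 (camera adjusted p = 0.0499, and adjusted p = 0.909 with an estimated correlation). Epcam, an epithelial adhesion molecule, rose by 0.76 ± 0.05 (SE, adjusted p = 0.0067), Esrp1, an epithelial splicing factor, by 0.89 ± 0.10, and Cdh1, which encodes E-cadherin, by 1.05 ± 0.21. Trp63, the transcription factor of stratified epithelium, rose by 0.52 ± 0.08, though a dimmer Trp63 probe set was called lower (−1.90 ± 0.36), and Wnt6 rose by 0.88 ± 0.16. Bcam, an adhesion molecule also found on blood and vessel cells, fell by 0.84 ± 0.09 (SE). Other probe sets of ectoderm members were called higher in 2 cases and lower in 1. The ectoderm list was not called without double mutant replicate 2 (median 0.18, adjusted p = 0.294), without wild type replicate 2 or 3 (adjusted p = 0.0563 and 0.0673), by the mean probe set per gene (0.14, adjusted p = 0.293) or by the second brightest probe set of 7 members (0.16, adjusted p = 0.468).

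The endothelial, blood and matrix lists were shifted down at the preset correlation. Of 14 endothelial genes 7 fell and 0 rose, with 9 and 0 adjusted over the list alone, and the median was −0.43 (camera adjusted p = 0.0064, and adjusted p = 0.909 with an estimated correlation). Pecam1, a junction protein of endothelium, fell by 1.98 ± 0.13 (SE, adjusted p = 0.0066), from 8.32 ± 0.19 (SD, n = 3) to 6.34 ± 0.08 (SD, n = 2), Tie1 by 0.96 ± 0.10, and Esam, Eng, Emcn, Plvap and Cldn5 differed by −0.55 to −0.38. The endothelial gene Egfl7, not called on its brightest probe set, was called higher on 3 others (0.30 to 0.67), the only calls on other probe sets in that list. The endothelial list was not called without double mutant replicate 2 (−0.47, adjusted p = 0.108) or by the mean probe set per gene (−0.42, adjusted p = 0.0551), and the second brightest probe set of the 3 members that had one gave the opposite sign (0.30, adjusted p = 0.632). Of 10 blood genes 4 fell and 0 rose, with 5 and 0 adjusted over the list alone, and the median was −0.42 (camera adjusted p = 0.0404, and adjusted p = 0.909 with an estimated correlation). Alas2, the erythroid enzyme of heme synthesis, fell by 1.89 ± 0.11 (SE), Rhag by 1.49 ± 0.23, the band 3 gene Slc4a1 by 1.04 ± 0.11 and the embryonic globin Hba-x by 0.45 ± 0.06. Blood genes had no call on other probe sets. The blood median was −0.24 without double mutant replicate 1 (adjusted p = 0.421) and −0.64 without double mutant replicate 2 (adjusted p = 0.0103), and the call was also lost without wild type replicate 1 or 3 (adjusted p = 0.121 and 0.0673), by the mean probe set per gene (−0.42, adjusted p = 0.0953) and by the second brightest of 3 members (−0.023, adjusted p = 0.996). Among macrophage genes C1qc (−0.74 ± 0.14) and Laptm5 (−0.67 ± 0.11) were lower of 13, with 5 lower adjusted over the list alone, and the list gave an adjusted p of 0.088. Laptm5 had another, dimmer probe set called higher (0.63 ± 0.12).

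The fibrillar matrix list had the widest median shift among the called lists, at −0.64, with 2 of 18 members lower, 0 higher and 17 of 18 below 0 (camera adjusted p = 0.0075, and adjusted p = 0.909 with an estimated correlation). Thbs1, a matrix glycoprotein gene, fell by 1.13 ± 0.20 (SE, adjusted p = 0.0315) and the collagen gene Col5a2 by 0.80 ± 0.15 (adjusted p = 0.0341), and each also fell on a second probe set (−2.56 and −0.96). Over the whole list 6 calls on other probe sets were lower and 1 was higher (Fn1, 2.42). Lum stood at 10.69 ± 0.47 and 11.64 ± 0.06 (adjusted p = 0.0509). The counts were the same adjusted over the list alone. Without double mutant replicate 2 the median was −0.15 and the call was lost (adjusted p = 0.396), as it was by the mean probe set per gene (−0.51, adjusted p = 0.0953) and by the second brightest of 12 members (−0.72, adjusted p = 0.231).

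**Figure D4:**
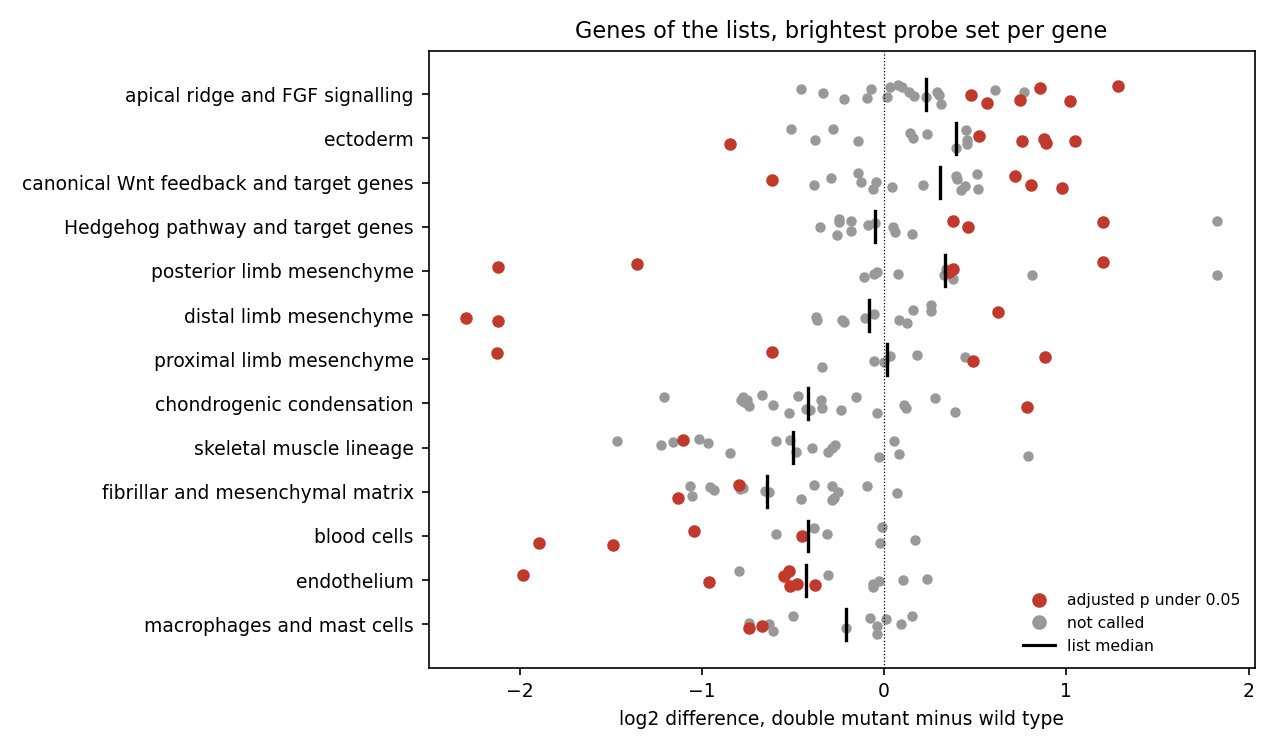
Log2 difference, double mutant minus wild type, of each member of 13 gene lists on its brightest probe set. Dark red points were called at an adjusted p under 0.05, grey points were not, and bars mark list medians, which run from −0.64 for the matrix list to 0.40 for the ectoderm list.

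Skeletal and muscle genes gave few calls on their brightest probe sets. In the chondrogenic list 17 of 22 members lay below 0 with a median of −0.42, but the 1 member called, the collagen gene Col27a1, was higher (0.78 ± 0.17, SE, adjusted p = 0.0467), and 0 passed adjusted over the list alone (list adjusted p = 0.323). Sox9, the master regulator of cartilage, stood at 9.84 ± 0.27 and 10.45 ± 0.14 (adjusted p = 0.0674), with another probe set called higher (0.49 ± 0.09), and Col2a1 at 10.67 ± 0.53 and 11.46 ± 0.34 (adjusted p = 0.186). Calls on other probe sets of the chondrogenic list were 1 higher, that of Sox9, and 5 lower. Myod1, which commits cells to muscle, fell by 1.10 ± 0.16 (adjusted p = 0.0194) and was the 1 member called of 18 in the muscle list (list median −0.50, adjusted p = 0.0786). Among tendon progenitor genes Osr2 was the 1 called of 11 (list adjusted p = 0.460). In the BMP list Id1 (0.42 ± 0.07) and Bmp7 (0.48 ± 0.09) rose, and Nog and Chrdl1 (−0.23 ± 0.04) fell, of 22 members, with 3 and 2 adjusted over the list alone (list adjusted p = 0.804, direction up, mean −0.06, median 0.05). On other probe sets the BMP list had 1 call higher and 11 lower, among them 2 of Bmp7 (−0.62 and −1.40). Bmp4 stood at 10.66 ± 0.23 and 10.75 ± 0.15 (adjusted p = 0.71) and Msx2 at 9.18 ± 0.09 and 9.41 ± 0.11 (adjusted p = 0.163). Muscle and tendon counts were the same adjusted over the list alone.

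In the retinoic acid list 4 of 12 members fell and 1 rose, with 5 and 2 adjusted over the list alone (list adjusted p = 0.460). Stra6, which takes retinol into cells, fell by 1.48 ± 0.11 (SE, adjusted p = 0.0073), and the nuclear receptor genes Rara, Rarb and Rarg differed by −0.94 to −0.88, while Cyp26a1, which degrades retinoic acid, rose by 0.79 ± 0.06 (adjusted p = 0.0073). In the hypoxia and glycolysis list P4ha1 (0.57 ± 0.07), Pdk1 (0.63 ± 0.09), Hk2 (0.35 ± 0.06) and Bnip3 (0.55 ± 0.11) rose and 0 fell of 17 (list adjusted p = 0.225). However, other probe sets of this list were called higher in 2 cases and lower in 7, among them the second P4ha1 probe set (−3.25 ± 0.30). The Notch target Hey1 rose (0.43 ± 0.09) and the ligand gene Dll4 fell (−0.86 ± 0.14) of 14 Notch members, with 4 and 2 adjusted over the list alone (list adjusted p = 0.460). The hypoxia counts were the same adjusted over the list alone.

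No list for a general process was called by camera. In the cell cycle list Bub1 rose (0.57 ± 0.06) and Mcm2 (−0.61 ± 0.08), Aurka (−0.42 ± 0.09) and Plk1 (−0.44 ± 0.09) fell of 22, with 2 and 3 adjusted over the list alone (list adjusted p = 0.883). In the cytosolic ribosomal list 3 of 57 rose and 3 fell, among them Rpl12 (2.11 ± 0.20), Rpl27a (−1.13 ± 0.07) and the kinase gene Rps6kb2 (−1.63 ± 0.09) (list adjusted p = 0.804). In the respiratory chain list 9 of 94 rose and 6 fell, with 9 and 12 adjusted over the list alone, and Ndufaf1 (1.24 ± 0.07) rose while Ndufa8 (−0.56 ± 0.06) fell (list adjusted p = 0.460). Calls on other probe sets were 9 higher and 1 lower for the ribosomal list and 15 higher and 6 lower for the respiratory chain list. For the cell cycle list they were 2 higher and 6 lower. The single calls were Ier3 (−0.44 ± 0.09) of 17 immediate early and heat shock genes (0 adjusted over the list alone, list adjusted p = 0.460), Dhcr7 (−0.48 ± 0.06) of 13 cholesterol genes (0.942), Bbc3 (−0.57 ± 0.10) of 11 p53 targets (0.623) and Ednrb (−1.12 ± 0.20) of 11 nerve and neural crest genes (0.883). In the trunk and somite list Meox2 rose (0.32 ± 0.06) and Foxc1 (−0.57 ± 0.08) and Meox1 (−0.47 ± 0.10) fell of 11 (list adjusted p = 0.961). Of 13 interferon genes limma called 0, and 0 reached an unadjusted p under 0.05 (list adjusted p = 0.460). The pair of targeted genes gave 0.460. Where no other count is given, it was the same adjusted over the list alone. With an estimated correlation camera called 0 of 33 lists, with 1 list at an unadjusted p under 0.05, and fry called the endothelial list alone (adjusted p = 0.0191). Fry's mixed test, which asks for change in either direction, called 24.

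Probe sets of 1 gene often disagreed. Of 1213 genes with at least 2 called probe sets, 271 had all of them higher, 487 all lower, and 455 (37.5%) had calls both ways. Tgfbr1, a receptor for TGF-beta chosen after its values were seen, fell by 4.76 ± 0.71 and 4.49 ± 0.46 (SE) on 2 probe sets, while its brightest differed by 0.28 ± 0.08. Hif1a, chosen likewise, fell by 4.50 ± 0.40 on 1 probe set, while its brightest probe set differed by 0.10 ± 0.06. Over 5286 genes with a second probe set above the median level, differences on the brightest and the second probe set correlated at r = 0.174 across genes, which are not independent replicates. Of 136 genes whose brightest probe set was called at 2-fold or more, the second was called the same way in 50, the opposite way in 16, and not called in 70. Probe sets with no gene symbol made up 30.3% of the higher calls (1186) and 4.78% of the lower calls (205), against 20.3% of all tested.

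**Figure D5:**
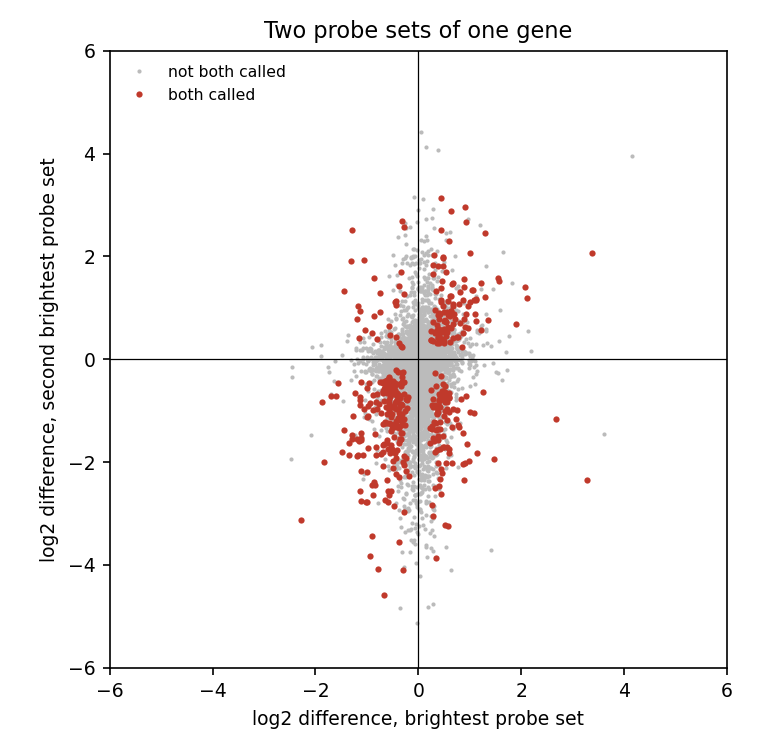
Log2 difference, double mutant minus wild type, on the second brightest probe set of a gene (vertical axis) against that on its brightest (horizontal axis), 1 point per gene, for 5286 genes. Of the 444 genes with both called, in dark red, 124 lie in the quadrants where the directions are opposite.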

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

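The tests of sample preparation, of RNA of both sexes and of a more distal cut were chosen after the result was seen, as was the comparison by the second brightest probe set, while the others were planned.

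Control transcripts outside the main measurement carried a signal in the double mutant arrays above the level in the wild type arrays. The poly-A spike-ins were higher in double mutants by at least 3.79 on the log2 scale for Dap, 1.73 for Thr, 1.81 for Phe and 1.55 for Lys, lower bounds since wild type levels lay near that of an absent control, in 2 of 2 double mutant arrays against each of 3 wild type arrays.

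Of 1213 genes with at least 2 called probe sets, 455 had calls in both directions. A preparation that differed between the groups may account for the disagreement, since the median spike-in difference was at least 1.77, although spike-ins can be added to some samples and not others without any effect on mouse RNA. The real split gave 8206 called probe sets and the highest of the other splits gave 0 with limma (201 to 3396 at an unadjusted p under 0.05), so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. An effect of genotype on whole transcripts moves all probe sets of a gene 1 way. Calls in both directions therefore argue against such an effect alone in these 455 genes. Preparation, effects of genotype on the ends of transcripts, which no test here decided, and a mixture of causes stay open. For these 5 arrays preparation and genotype cannot be told apart.

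Xist and the Y-linked genes were both high in each double mutant array, although the labels describe unpooled embryos. The planned test of a labelling difference that raised the Xist probe sets decided nothing. Of 4315 genes with at least 3 probe sets, 0 other than Xist rose on all of them by as much as the least moved Xist probe set (4.70 on the log2 scale). That bar came from Xist itself, and only 5 single probe sets outside Xist reached it. A count of 0 was therefore likely with or without such a difference. On 1427262_at and 1427263_at, however, wild type replicates 2 and 3 stood at 3.41 to 3.75, near Trpn (3.07). The double mutant arrays stood at 10.44 and 9.48 on 1427262_at, against 11.18 in wild type replicate 1. On 1427263_at they stood at 8.44 and 8.85, against 8.45. Labelling acts on RNA that is present, so these levels argue against a labelling difference alone in both double mutant arrays. A mixture of RNA from both sexes may account for the pattern. Xist and Y-linked levels, each relative to the wild type arrays that have them, were added on the linear scale. The sums were 1.91 and 1.66 with the brightest Xist probe set, 1.44 and 1.27 with 1427262_at and 1.84 and 2.29 with 1427263_at. If intensity is proportional to RNA amount, which was not tested, a mixture gives a sum near that of the wild type arrays (at most 1.04). The sums lie above the range set for a mixture, by little for 1427262_at. They differ between Xist probe sets in the same arrays and rest on that proportionality, so they do not count against a mixture. Xist and Y-linked levels were both far above those of arrays that lack them, so the test leaves a mixture open. A sex chromosome constitution with both, and an effect of genotype on Xist, were not tested.

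With camera at the preset correlation the ridge and ectoderm lists were shifted up and the endothelial, blood and matrix lists down in double mutants, and with an estimated correlation 0 of these 5 were called (adjusted p = 0.909 each). A more distal cut of the mutant limbs may shift tissue shares this way, but the median difference of the distal list minus that of the proximal list was −0.10 (95% bootstrap interval over list members −0.59 to 0.36), which leaves it open. That interval treats genes as independent and carries no variation between embryos. Probe set position rather than transcript level also stays open, since 3 of the 5 lists kept the sign of their median with the second brightest probe set per gene, and the ridge list (−0.46, from 12 of 23 members) and the endothelial list (0.30, from 3 of 14) did not. An effect of genotype on signalling or tissue make-up is the biological explanation the design offers, and nothing here separates it from the preparation difference.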

How the results depend on the processing

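The second brightest probe set per gene, the fit on probe sets with 1 symbol and the list tests without genes called in both directions were chosen after the data were seen, and the other settings were fixed in advance. The cause of each change was not tested, except that fits by gene hold fewer tests and fits with an array left out hold fewer arrays. Fits with a covariate also have fewer residual degrees of freedom. The 3' to 5' covariate, the mean of Gapdh and Actb, itself followed genotype (0.46 and 0.36 in double mutants, 0.03, 0.07 and 0.31 in wild type). Calls lost with it therefore do not show that RNA quality accounts for the differences.

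The 8206 called probe sets became 2676 by the brightest and 3905 (1433 higher and 2472 lower) by the mean probe set per gene, 2083 by the second brightest (589 higher and 1494 lower), 3874 with the Y-linked covariate, 1617 at an adjusted p under 0.01, and 0 with the 3' to 5' covariate (limma, 9633 at an unadjusted p under 0.05). With 1 array left out the count ran from 0 to 5108. It was 0 without double mutant replicate 1 (14059 at an unadjusted p under 0.05), 3826 without double mutant replicate 2, 2939 without wild type replicate 1, 0 without wild type replicate 2 (11115 at an unadjusted p under 0.05) and 5108 without wild type replicate 3, and a lone double mutant array was assumed to vary like the wild type arrays. With equal array medians 9625 were called, 3776 higher and 5849 lower, and with 1 symbol 6965, 2793 higher and 4172 lower. The numbers in the sample names were shared by only 2 pairs, whose deviations from the group means correlated at 0.09 and 0.12. The deviations of the 2 double mutant arrays mirror each other, so these values cannot show whether the pairs share more than a number. With a replicate block over these pairs the count was 2351.

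The 5971 probe sets past an unadjusted p under 0.01 and 1.5-fold became 3750 at 2-fold, 3480 with the 3' to 5' covariate, 1322 by the brightest, 1853 by the mean and 1491 by the second brightest probe set per gene, and 3524 to 5228 with 1 array left out. The lowest values came without double mutant replicate 1 (3524) and without wild type replicate 2 (3601).

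The 5 called lists became 9 with the 3' to 5' covariate, 3 with array weights, 3 with the replicate block, 1 by fry and 24 by its mixed test. Camera called 0 by the mean probe set per gene, 0 by the second brightest and 0 with an estimated correlation, with 6, 4 and 1 lists at an unadjusted p under 0.05. With 1 array left out 2 to 8 lists were called, 8 without double mutant replicate 1, 2 without double mutant replicate 2 and 3 without wild type replicate 3.

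For the ridge list the call was lost with an estimated correlation and by fry (median 0.23), and by the mean probe set per gene (0.0075), and the second brightest, which 12 of 23 members had, gave −0.46. Its leave-one-out medians ran from 0.12, not called and without double mutant replicate 2, to 0.30. The endothelial call was lost with an estimated correlation (−0.43) and by the mean (−0.42), and the second brightest gave 0.30 from 3 of 14 members, with leave-one-out medians from −0.35 to −0.47, the latter not called and without double mutant replicate 2. The matrix call was lost with an estimated correlation and by fry (−0.64), by the mean (−0.51) and by the second brightest (−0.72, 12 of 18 members), with leave-one-out medians from −0.15, not called and without double mutant replicate 2, to −0.98, without double mutant replicate 1. The blood call was lost with the 3' to 5' and Y-linked covariates (−0.42 each), array weights and the replicate block (−0.40 each), an estimated correlation, fry and the mean (−0.42 each) and the second brightest (−0.023, 3 of 10 members), with leave-one-out medians from −0.24 to −0.64. The ectoderm call was lost with array weights (0.37), an estimated correlation, fry and the filter on dim probe sets (0.40 each), the mean (0.14), the replicate block (0.42), the second brightest (0.16, 7 of 17 members) and without genes called in both directions (0.32), with leave-one-out medians from 0.18 to 0.44. Without double mutant replicate 1, wild type replicate 1 or wild type replicate 3 the blood call was lost (adjusted p = 0.421, 0.121 and 0.0673), and without double mutant replicate 2, wild type replicate 2 or wild type replicate 3 the ectoderm call (adjusted p = 0.294, 0.0563 and 0.0673).

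Sost 1450179_at was no longer called with the 3' to 5' covariate (−2.04) or the replicate block (−2.18), and ranged from −2.03 to −2.32 with 1 array left out. Sostdc1 1460250_at was no longer called with the 3' to 5' covariate (−1.99), the Y-linked covariate (−2.25) or the replicate block (−2.36), and ranged from −1.82 to −2.89 with 1 array left out. The Sost call was lost without either double mutant array or wild type replicate 2, and the Sostdc1 call without double mutant replicate 1 or any wild type array.

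Among named genes, the mean probe set per gene turned Etv5 (−1.53), P4ha1 (−1.34), Trp53inp1 (−1.30) and Laptm5 (0.035). The second brightest probe set turned Taf15 (−1.46), Zfp945 (−2.35), Vps52 (−1.16), Ptch1 (−1.36), Smo (−0.62), Wnt5a (−0.066), Lef1 (−0.94), Tbx5 (−1.89), Etv5 (−1.49), P4ha1 (−3.25), Trp53inp1 (−2.76), Sox9 (0.49), Laptm5 (0.094) and Mcm2 (0.056). Calls on 85 named genes were lost without double mutant replicate 1, without wild type replicate 2, or with the 3' to 5' covariate, and on 59 with the replicate block. With equal array medians Ptch1, Smo, Wnt5a, Id1, Chrdl1, Meox2, Hk2 and Hey1 were no longer called. The simulated data, with only 200 changed probe sets, recovered 14% of changes of 1.5-fold.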

Other observations

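The selection of genes whose probe sets agree was made after the result was seen, as was the split of gene neighbours by locus, and the test of neighbours together was planned.

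In 5286 genes at least 2 probe sets lay above the median level, and all of these were called higher in 65 genes and lower in 159. Members of the fixed lists among them were Wnt6, Rps27l, Cox6c and Cox8a, all higher, and Thbs1, Ednrb, Rarg, Col5a2, Hoxc5 and Fzd6, all lower. Wnt6, a Wnt ligand of the limb ectoderm, rose by 0.88 ± 0.16 (SE, adjusted p = 0.0347) and 1.16 ± 0.08 (adjusted p = 0.0072) on its 2 probe sets. Ednrb, the endothelin receptor of neural crest cells, fell by 1.12 ± 0.20 and 1.52 ± 0.14. Rarg, a retinoic acid receptor, fell by 0.90 ± 0.15 and 3.43 ± 0.24, and the limma adjusted p of the probe sets of these 3 genes ran from 0.0069 to 0.0347.

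Long noncoding RNAs from imprinted regions stood among the genes that rose on all such probe sets. Kcnq1ot1, the antisense RNA of the Kcnq1 domain, rose by 1.55 ± 0.33 and 1.59 ± 0.34 (SE). Snhg14, a host of small nucleolar RNAs, rose by 1.53 ± 0.12 and 1.56 ± 0.20, and Mirg, a microRNA host, by 1.22 ± 0.24 and 1.48 ± 0.21. These 3 genes were picked by eye from the 65, and no enrichment was tested.

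A chromosome segment carried with the targeted alleles may add calls near the targeted loci. Of 200 measured genes, 50 on either side of each locus, 40 were called (20%), against 14.7% of 17938 other genes (Fisher's exact test, one-sided p = 0.0248). The Sost neighbours held 24 calls in 100 genes (Fisher's exact test, one-sided p = 0.0092) and the Sostdc1 neighbours 16 in 100 (one-sided p = 0.394). In 10000 random pairs of windows of the same size the median was 29 called genes, and a share of 0.0486 held as many as 40. The test does not separate strain differences near the loci from clusters of genes that respond together.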
